A study of Mus musculus with 36 samples.

How the data were processed

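RNA was measured in 36 libraries of mouse embryonic stem cells. The titles and descriptions of the samples place them in 12 groups of 3: cells transfected with LiTEC or wild-type (WT) cells, with or without 30 min of blue light, and RNA taken 0, 1 or 4 h after that period. Titles also give a replicate number and a batch: replicate 1 of every group is in batch 1, and replicates 2 and 3 are in batch 2. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded poly(A) mRNA kit.

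The deposited table holds raw counts per gene, whole numbers that sum to a different total in each library. Per the submitters' processing notes, FastQC and featureCounts were among the tools and mm10 (GRCm38) was the genome build. The aligner, the strand setting, the treatment of reads that match several places and all versions are not given in the sources used here. Counts of genes that overlap another gene on either strand and of members of near-identical families are therefore uncertain, and the text marks some of these and not all. The table held 54842 genes, and the series' own name map gave a symbol for every one of them. No column outside the 36 libraries was present. Coordinates are 1-based positions in GRCm38 from the GENCODE M21 annotation, which matched 18179 of the 18193 tested genes by identifier.

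Library totals ran from 11132970 to 21842256 counts. Genes were kept for testing with edgeR's filterByExpr on the 12 groups with its minimum count of 10, which left 18193 genes, with 99.8792% of the counts in the library where their share was lowest. Libraries were scaled by TMM. All 36 libraries were fitted together with a mean for each group and a term for batch, with 23 residual degrees of freedom, using edgeR's quasi-likelihood functions glmQLFit and glmQLFTest (edgeR 4.0.16, limma 3.58.1, R 4.3.3). P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Group levels are given as CPM (counts scaled to a library of 1e6) on TMM-scaled library sizes, as mean ± SD.

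There were 16 gene-level comparisons: light minus dark within a genotype at each time (6), the difference of that effect between LiTEC and WT at each time (3), LiTEC minus WT over the dark libraries (1), a change of the light effect over the 3 times within a genotype (2, an F test), a change among the dark libraries over time within a genotype (2, an F test), and the mean light effect over the times within a genotype (2). In addition, 31 gene lists with 533 members, of which 493 were measured, were fixed before the data were examined. They cover stress and signalling (immediate early genes, heat shock, NRF2 oxidative stress, metallothioneins and zinc, p53 targets, ATF4 targets, unfolded protein response, interferon, hypoxia and glycolysis, ERK feedback, STAT3 targets, Wnt targets, circadian clock, cholesterol synthesis), the transcription machinery (Mediator, RNA polymerase II, pause release and elongation), cell cycle and growth (G1/S, G2/M, ribosomal proteins, mitochondrially encoded mRNAs), cell states (naive and formative pluripotency, 2-cell-like cells, germline, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, fibroblasts and feeders) and Y-linked genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 31 lists of a comparison, and again with an estimated correlation. For each list the number of members that passed was also counted with p-values adjusted over the list alone. Medians of the LiTEC minus WT log2 fold change per chromosome used tested genes with a mean of at least 1 CPM; the plan made before the data were examined named all tested genes, and medians over these are given beside them.

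The genes named below follow a rule set before the data were examined. All called genes are named where there are at most 24. Otherwise the rule takes the 12 higher and the 12 lower genes with the largest absolute log2 fold change among those with an established symbol and a mean of at least 5 CPM in a compared group; for F tests, which have no direction, it takes the 24 with the smallest p. It adds up to 4 members of each list that was called or had a called member, and 13 fixed genes: Pou5f1, Nanog, Sox2, Klf4, Esrrb, Fos, Egr1, Hspa1a, Hspa1b, Hmox1, Cdkn1a, Actb and Gapdh. Some genes that the rule selects are not named, and they remain in all counts.

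The alternatives tried were a 3-level replicate block in place of batch, no batch term, a batch effect of its own in each genotype, batch 2 alone, RLE size factors, DESeq2 1.42.0, no expression filter, a mean of at least 5 CPM, a fit of the compared groups only, a fold threshold of 1 on the log2 scale, and leaving out each library in turn. A replicate block per genotype and a fit without the ribosomal RNA loci Gm26917 and Gm42418 were added after the data had been seen. Replicate numbers pair the libraries: the labels tie number 1 to batch 1, and in each comparison the deviations from the group means of same-numbered libraries of different groups correlated across genes at 0.200 or more. The main fit holds only the batch term, so it does not pair replicates 2 and 3 across groups. Same-numbered libraries are treated as related only with the replicate block, and counts with it are printed where they move a count by over 1.5 times. No pair of libraries of a group agreed within counting noise (chi-square per degree of freedom of at least 3.82), so none was taken as a repeat of another and each was counted as 1 replicate. That does not show that they came from separate cultures. When a library is left out of a group of 3, or batch 2 is used alone, the spread is still pooled over all groups. Log2 fold changes given for batch 1 were taken from CPM with 0.5 CPM added, which shrinks those of genes with low counts.

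The tests were run on simulated data made from the real mean of each gene over all libraries and the real library sizes. Genes were drawn independently, without a batch effect or a relation between same-numbered libraries, and only genes of at least 5 CPM were changed. The shares below therefore need not hold for the real libraries. For the light effect in LiTEC at 0 h, 82% of 100 genes changed by 1.5-fold and 99% of 100 genes changed by 2-fold were called, with 9 false calls among 190 (4.74%; 18193 genes). The difference of light effects at 0 h recovered 61% and 89% at these fold sizes, with 12 false calls among 162 (7.41%), and LiTEC against WT recovered 70% at 1.2-fold and 100% at 1.5-fold, with 10 among 180 (5.56%). Without any simulated change, 5 comparisons in WT gave at most 1 call. In the simulated list test, camera called the raised set and 0 of 20 unchanged sets. Because the simulated genes were not correlated, that test does not show how camera treats correlated lists.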

Results

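The libraries came from mouse embryonic stem cells kept in serum-free medium with inhibitors of MEK and GSK3β and leukaemia inhibitory factor, a culture that favours naive pluripotency. Cells transfected with LiTEC, the construct of a study on light-induced targeting, were set beside wild-type cells. Every culture had been given doxycycline at 2 µg/ml for 2 days. Some cultures then stood on a panel of blue LEDs for 30 min and the others did not, and RNA was taken 0, 1 or 4 h afterwards. Each of the 12 groups held 3 libraries, with total counts from 11132970 to 21842256 and a mean of 16774000 ± 2094290 (SD, n = 36). The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be partly technical. A library with a large share of counts on a ribosomal RNA locus stood apart: Gm26917 took 26.1% of counts in replicate 3 of dark WT cells at 4 h, 16.3% in replicate 1 of lit LiTEC cells at 0 h, and 9.87% in the median library.

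The design asks how blue light alone changes transcripts and whether LiTEC alters that response. Straight after light, WT cells carried far more inducible Hsp70 mRNA. Hspa1a, a heat shock chaperone gene, rose from 0.815 ± 0.232 to 49.5 ± 20.8 CPM (n = 3 each), a log2 fold change of 5.85 ± 0.48 (SE; edgeR adjusted p = 2.97e-10), and Hspa1b rose by 3.85 ± 0.39. The long non-coding RNA Gas5 fell by a log2 fold change of −0.96 ± 0.07 (adjusted p = 6.79e-12), Snhg4 from 162 ± 21.7 to 62.0 ± 13.8 CPM (−1.40 ± 0.10) and Dancr by 1.69 on the log2 scale. In total 520 of 18193 genes were called, 302 higher and 218 lower.

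Of the 20 measured heat shock genes, 4 rose in WT and none fell: Hspa1a, Hspa1b, Hsph1 (0.78 ± 0.12) and the Hsp40 cochaperone gene Dnajb1 (0.73 ± 0.09). Of the list, 6 passed when adjusted over the list alone. Camera called the list (adjusted p = 2.54e-11; adjusted p = 0.0163 with an estimated correlation). Of 27 immediate early genes, 3 rose, Gadd45b (0.84 ± 0.20), the mRNA decay factor gene Zfp36 (0.73 ± 0.16) and Junb (0.50 ± 0.12). When adjusted over the list alone 6 passed (camera adjusted p = 0.00108; adjusted p = 0.109 with an estimated correlation). Fos and Egr1 were not called (0.43 ± 0.40 and 0.97 ± 0.32). Of 34 cytosolic ribosomal protein genes 4 fell, Rpl24 (−0.95 ± 0.17), Rpl3 (−0.35 ± 0.07), Rps20 (−0.34 ± 0.08) and Rpl7 (−0.17 ± 0.05). Rpl24 had a mean of 5.86 CPM over all libraries, against 483, 406 and 708 for the others. Its value, here and below, may thus not stand for ribosomal protein mRNAs. Rpl3 and Rps20 also hold small nucleolar RNA genes, and they are among the 6 of 214 protein-coding hosts of such genes called lower here. When adjusted over the list alone the number of ribosomal protein genes was 10 (camera adjusted p = 9.98e-12, and adjusted p = 0.0606 with an estimated correlation). Of 26 pluripotency genes Sox2 (−0.31 ± 0.07) and Tdgf1 (−0.31 ± 0.08) fell, and 5 passed when adjusted over the list alone (camera adjusted p = 6.24e-05; adjusted p = 0.0606 with an estimated correlation). Pou5f1 (−0.09 ± 0.10), Nanog (−0.32 ± 0.10), Klf4 and Esrrb were not called. Among 17 G2/M genes the mitotic cyclin gene Ccnb1 (−0.35 ± 0.06) and the kinase gene Cdk1 (−0.29 ± 0.06) fell. The same number passed when adjusted over the list alone (camera adjusted p = 0.00627; adjusted p = 0.147 with an estimated correlation). Single members of other lists were called: Phlda1 and Spry1 (0.55 ± 0.15) of the ERK feedback list and the zinc exporter gene Slc30a1 (0.49 ± 0.13) rose. Ppp1r15a (−0.39 ± 0.10), a phosphatase subunit gene of the integrated stress response, and the ribonucleotide reductase gene Rrm2 (−0.19 ± 0.05) fell.

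The remaining genes with the largest changes in WT were Pla2g4c (1.09 ± 0.21), Rimbp3, Ccpg1, Swt1 (0.82 ± 0.09), Dpm1, Map2k3os and Dyrk1b, which rose. Those that fell were Lrrc75aos2 (−2.07 ± 0.17), Snord43 (−1.70 ± 0.18), Snord49a (−1.53 ± 0.22), Clcn1, C78283, Snhg8 (−1.09 ± 0.16), Rab26os and Snhg6 (−0.98 ± 0.13). Several of these cannot be told from their neighbours. Hspa1a (chromosome 17, 34969190 to 34972156) and Hspa1b (34956436 to 34959238) are near-identical copies, Snord43 lies inside Rpl3 and Snord49a inside 2410006H16Rik on the same strand, Lrrc75aos2 is antisense to Lrrc75a, and Rab26os overlaps Rab26 on the opposite strand. Of 141 genes called in batch 2 alone, 136 had the same direction in batch 1. Hspa1a changed by 5.69 in batch 1, where 0.5 CPM was added to 69.72 (lit) and 0.8634 CPM (dark). It changed by 5.57 in batch 2 without that addition, so these 2 values are not comparable in size. Dancr changed by −1.83 in batch 1 and −1.60 in batch 2. The number of calls was 870 with the replicate block, 277 without a batch term, 178 when only the compared groups were fitted and 141 in batch 2 alone. It fell to 268 without lit replicate 1, 301 without lit replicate 2 and 233 without dark replicate 3.

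In LiTEC cells, 170 genes were called straight after light, 73 higher and 97 lower. Hspa1a rose from 0.713 ± 0.357 to 5.15 ± 2.35 CPM (log2 fold change 2.89 ± 0.60, adjusted p = 0.0123, n = 3 each), Hspa1b by 1.72 ± 0.43 and Dnajb1 by 0.63 ± 0.09 (adjusted p = 0.000434). Snhg4 fell from 148 ± 10.4 to 80.4 ± 3.50 CPM (−0.88 ± 0.10, adjusted p = 4.38e-06) and Dancr by 0.68 on the log2 scale. These 3 were the called heat shock genes of 20, with none lower and 6 when adjusted over the list alone (camera adjusted p = 5.60e-10; adjusted p = 0.0204 with an estimated correlation). Of 27 immediate early genes Gadd45b (0.93 ± 0.20) and Arc (0.42 ± 0.10) rose. When adjusted over the list alone 7 passed (camera adjusted p = 3.29e-06; adjusted p = 0.0204 with an estimated correlation). Camera also called the unfolded protein response list (adjusted p = 0.00448; adjusted p = 0.537 with an estimated correlation) and p53 targets (0.0125; adjusted p = 0.537 with an estimated correlation). No member of either was called. Dnajb9 was 0.41 ± 0.12 and Aen 0.21 ± 0.07, and 1 and 0 members passed when adjusted over the list alone. Slc30a1 rose (0.57 ± 0.13). The other genes with the largest rises were the transcriptional coregulator gene Sertad1 (0.74 ± 0.17), Nfkbid, the kinase gene Ripk4 (0.69 ± 0.12), Thap2, Cdkn2aip (0.62 ± 0.10), Rdh10 and Zfp46. Those with the largest falls were Clcn1 (−1.21 ± 0.31), AA386476, Itgb1bp2, Lcmt2 (−0.92 ± 0.18), Naaladl1, Zfp941 (−0.85 ± 0.13), the p53-induced long non-coding RNA Trp53cor1 (−0.78 ± 0.17), Bphl, Lrrc29 and Zfp386 (−0.63 ± 0.11). Pou5f1, Nanog, Sox2 (−0.19 ± 0.07), Klf4, Esrrb, Fos, Egr1, Hmox1, Cdkn1a, Actb and Gapdh were not called.

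The 3 genes called in batch 2 alone had the same direction in batch 1, too few for a check of the 170. Hspa1a was 2.43 in batch 1, where 0.5 CPM was added to 6.705 (lit) and 0.8393 CPM (dark). It was 2.80 in batch 2 without that addition, so these 2 values are not comparable in size. The count was 290 with the replicate block, 73 without a batch term, 71 when only the compared groups were fitted and 3 in batch 2 alone. Without lit replicates 1 or 3 or dark replicates 1, 2 or 3 it was 40, 70, 85, 69 and 55. Snhg4, Dnajb1, Ripk4, Cdkn2aip, Zfp941 and Zfp386 stayed called without each of the 6 libraries in turn. Hspa1a missed the threshold without lit replicate 1 or 3 or dark replicate 1 or 2, and Hspa1b without any of the 6.

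Called genes of the 2 genotypes overlapped although they share no library. In detail, 42 genes were higher in both, against 1.21 from independent lists, and 40 were lower in both, against 1.16. Such numbers from independent lists, here and below, take all genes as equally likely to be called and the libraries as unrelated. Same-numbered libraries are related, so these numbers may be too low. A test of the difference between the light effects at 0 h called 4 genes. The LiTEC change was above that of WT for Lrrc75aos2 (difference 1.70 ± 0.23, adjusted p = 0.000189), Snord43 (1.45 ± 0.25, adjusted p = 0.0134) and Gas5 (0.52 ± 0.09, adjusted p = 0.0163). It was below it for the non-coding RNA B830012L14Rik (−0.82 ± 0.15, adjusted p = 0.0175). Gas5 (chromosome 1, 161034422 to 161038539) had fallen by 0.44 in LiTEC and by 0.96 in WT. The difference was 0.74 in batch 1 and 0.40 in batch 2. For Hspa1a (−2.96 ± 0.96, adjusted p = 0.68) and Hspa1b (−2.14 ± 0.59, adjusted p = 0.663) the difference did not pass. Camera called 9 lists with a more positive change in LiTEC, namely ribosomal proteins (adjusted p = 2.60e-13), p53 targets, unfolded protein response, hypoxia and glycolysis, G2/M, G1/S, NRF2, naive pluripotency and RNA polymerase II. None passed with an estimated correlation (lowest adjusted p = 0.113, for ribosomal proteins with an estimated correlation). The members of these lists to pass when adjusted over the list alone were 1 ribosomal protein gene and 2 G2/M genes. The count was 7 with the replicate block, 9 with a block per genotype, 31 without an expression filter and 0 in batch 2 alone by edgeR. DESeq2 called 6, and 1129 genes had an unadjusted p below 0.05. It was 2, 2, 1, 1 and 1 without lit LiTEC replicate 1 or 2, dark LiTEC replicate 2, lit WT replicate 1 or dark WT replicate 3. Of the 4 genes, Lrrc75aos2 passed without each of the 12 libraries in turn.

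**Figure D1:**
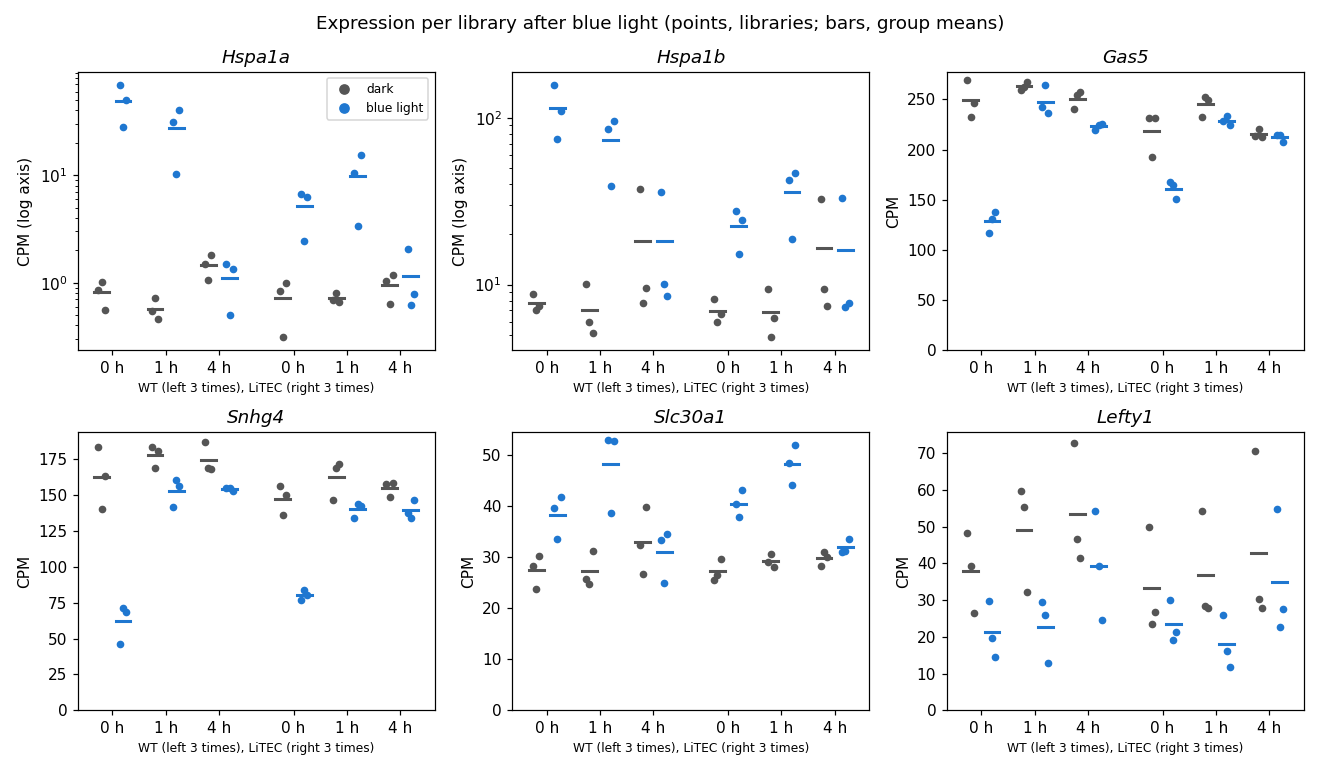
CPM of 6 genes in each of the 36 libraries (points; the bar is the group mean), by genotype, light and hours after light. Hspa1a and Hspa1b were higher in lit libraries of both genotypes at 0 and 1 h and not at 4 h, and Gas5 and Snhg4 were lower in lit libraries at 0 h.

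One hour after light, fewer genes differed and the lists of both genotypes were alike in kind. There were 21 genes in LiTEC (15 higher, 6 lower) and 52 in WT (32 higher, 20 lower). Of these 13 were higher in both (0.0264 from independent lists) and 4 were lower in both (0.0066). Hspa1a was still raised, by 3.73 ± 0.54 in LiTEC (9.75 ± 6.06 against 0.715 ± 0.0699 CPM) and 5.55 ± 0.52 in WT (27.3 ± 15.4 against 0.573 ± 0.132 CPM, n = 3 each). Hspa1b was at 2.46 ± 0.41 and 3.46 ± 0.40. Socs3, the feedback inhibitor of cytokine signalling through STAT3, rose by 0.93 ± 0.10 and 0.97 ± 0.10 (adjusted p = 3.65e-07 and 9.88e-08). Banp (chromosome 8, 121949750 to 122029258), a nuclear protein gene, rose by 0.83 ± 0.07 and 0.78 ± 0.08. Lefty1, an inhibitor of Nodal signalling, fell by 1.03 and 1.12 on the log2 scale (SE 0.21 and 0.20).

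Heat shock genes were called as a list in both genotypes, with Hspa1a, Hspa1b and Dnajb1 called of 20 in each and 3 and 4 when adjusted over the list alone (adjusted p = 0.00326 in LiTEC and 0.00694 in WT with an estimated correlation). In the unfolded protein response list of 18, the chaperone gene Hspa5 (0.38 ± 0.08) and the transcription factor gene Xbp1 (0.31 ± 0.07) rose in LiTEC and Herpud1 (0.92 ± 0.20) and Xbp1 (0.32 ± 0.06) in WT. In LiTEC and WT 10 and 2 members passed when adjusted over the list alone (adjusted p = 0.00323 and 0.0311 with an estimated correlation). Of 9 STAT3 targets Socs3 and Junb (0.67 ± 0.12 and 0.83 ± 0.12) rose in both genotypes, the same 2 when adjusted over the list alone (adjusted p = 0.00221 and 0.00694 with an estimated correlation). The p53 target list of 19 held no called gene in LiTEC and Btg2 (0.49 ± 0.10) in WT. The numbers were 6 and 4 when adjusted over the list alone (adjusted p = 0.00326 and 0.00922 with an estimated correlation). Slc30a1 was the 1 called gene of the 6 zinc genes in each genotype, all genes or list alone (0.72 ± 0.13 and 0.81 ± 0.13; adjusted p = 0.00756 and 0.0114 with an estimated correlation). Junb in LiTEC, and Junb and Btg2 in WT, were the called immediate early genes of 27. There were 5 and 3 higher when adjusted over the list alone (adjusted p = 0.0252 and 0.278 with an estimated correlation). Camera called the list of 17 G2/M genes lower in both, with no member called over all genes or over the list alone, and the call was kept in WT but not in LiTEC (adjusted p = 0.00714 and 0.192 with an estimated correlation; in LiTEC and WT, Plk1 −0.12 ± 0.06 and −0.18 ± 0.06). Camera also called ATF4 targets higher (adjusted p = 0.738 and 0.727 with an estimated correlation) and hypoxia and glycolysis lower (adjusted p = 0.738 and 0.278 with an estimated correlation) in both genotypes. Cholesterol synthesis was called lower in WT (adjusted p = 0.748 with an estimated correlation). None of these had a called member. With the replicate block, G1/S genes were also called in LiTEC (adjusted p = 0.0452 in place of 0.0739; adjusted p = 0.433 with the block and an estimated correlation).

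The other called genes in LiTEC included Rsrp1 (0.55 ± 0.06), the transcription factor gene Zfp296 (0.77 ± 0.10), Gtf2ird1, Map3k2, Nemp1 and Csrnp2, which rose. Those that fell included Camk2g (−0.38 ± 0.07), AC160637.1 (−0.59 ± 0.09), the olfactory receptor gene Olfr984 and Trpc5os (−1.97 ± 0.29). In WT the genes with the largest changes also included Zfp296 (0.55 ± 0.09), Hs3st3b1, Csrnp2 and Dedd2, higher. The lower ones included Chst15 (−0.94 ± 0.19), the pluripotency transcription factor gene Foxd3 (−0.76 ± 0.16), the receptor gene Notch3 (−0.74 ± 0.13), AC160637.1 (−0.71 ± 0.09), Hist2h2ac, Smad7 (−0.45 ± 0.08), Dnajc27, Rnf165, Camk2g and Zfp827. AC160637.1 lies within Pkm on the same strand and Trpc5os opposite Trpc5, so their counts are uncertain. The 7 and 11 genes called in batch 2 alone in LiTEC and WT had the same direction in batch 1, with Banp at 0.69 and 0.90 in LiTEC and 0.68 and 0.82 in WT. The block gave 60 and 111 calls, no batch term 10 and 15, compared groups alone 28 and 20, batch 2 alone 7 and 11, and DESeq2 45 in LiTEC. In LiTEC the count was 35, 9 and 10 without lit replicate 2, lit replicate 3 or dark replicate 3. In WT it was 19, 16, 28, 20 and 22 without lit replicate 1 or 3 or dark replicate 1, 2 or 3. No gene passed the test of a difference between genotypes at 1 h by edgeR or DESeq2 (378 genes at an unadjusted p below 0.05; 4 without an expression filter), and no list did.

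**Figure D2:**
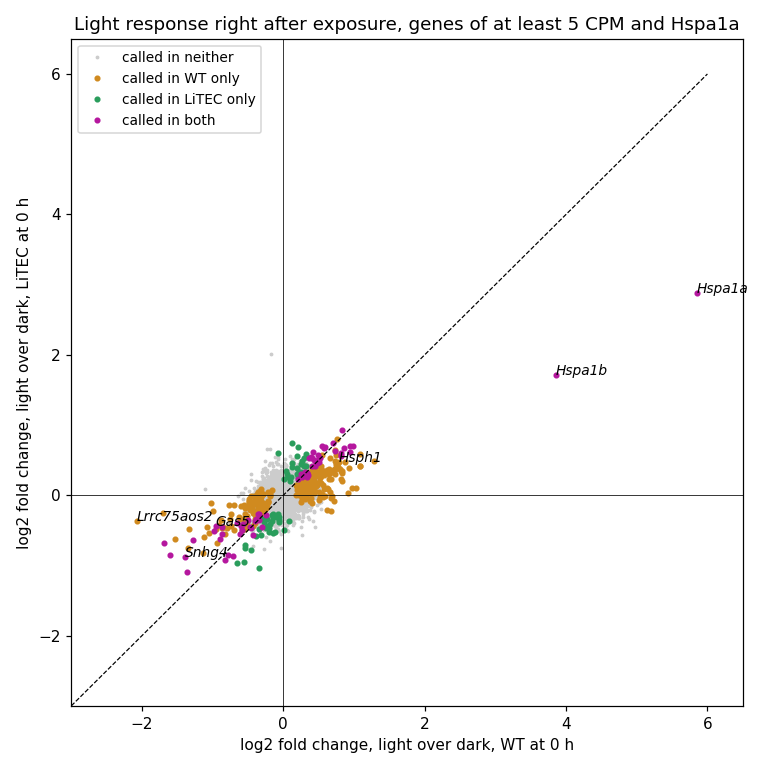
Log2 fold change with light at 0 h in WT (x axis) and LiTEC (y axis), for genes of at least 5 CPM and Hspa1a, coloured by the genotype in which they were called. The dashed line marks equal changes, and Hspa1a (5.85 in WT, 2.89 in LiTEC) and Lrrc75aos2 (−2.07 and −0.37) lie away from it on the WT side.

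By 4 h the inducible Hsp70 genes no longer differed between lit and dark cells (Hspa1a 0.27 ± 0.72 in LiTEC and −0.36 ± 0.67 in WT). Hspa1b was uneven between batches at this time in both light conditions, at 18.1 ± 15.4 CPM lit and 18.2 ± 16.6 CPM dark in WT. In LiTEC, Cbr3 (chromosome 16, 93683215 to 93690990), a carbonyl reductase gene, rose from 5.44 ± 1.19 to 10.7 ± 0.384 CPM (0.99 ± 0.16, adjusted p = 0.007, n = 3 each; 0.71 in batch 1 and 1.09 in batch 2), and the predicted gene Gm48639 fell (−1.60 ± 0.29, adjusted p = 0.0461). In WT no gene was called by edgeR, with 1484 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0545; DESeq2 called 18.

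Camera called the NRF2 oxidative stress list of 19 higher in both genotypes at 4 h, a call kept in LiTEC and lost in WT (adjusted p = 0.0334 and 0.0689 with an estimated correlation). No member was called over all genes, and 4 were higher in each genotype when adjusted over the list alone. The glutathione synthesis gene Gclm was 0.33 ± 0.07 in LiTEC and 0.30 ± 0.07 in WT, the quinone reductase gene Nqo1 0.38 ± 0.10 and 0.40 ± 0.10, and Srxn1 0.36 ± 0.12 and 0.39 ± 0.11. Of 20 cholesterol synthesis genes none was called over all genes in either genotype, and 8 in LiTEC and 6 in WT were lower when adjusted over the list alone; camera called the list lower in both, and neither call was kept (adjusted p = 0.0719 and 0.208 with an estimated correlation; Insig1 −0.28 ± 0.08 and −0.34 ± 0.08). Of 21 hypoxia and glycolysis genes none was called over all genes, and 2 and 6 were lower when adjusted over the list alone; camera called this list lower in both as well, and again neither call was kept (adjusted p = 0.405 and 0.208 with an estimated correlation; Pdk1 −0.20 ± 0.06 and −0.29 ± 0.06). In LiTEC camera further called the unfolded protein response (6 when adjusted over the list alone; Hspa5 0.28 ± 0.08), heat shock (1), zinc (1) and ribosomal protein (0) lists higher and Wnt targets (0) lower, with adjusted p = 0.213, 0.213, 0.0669, 0.366 and 0.323 with an estimated correlation. In WT it called formative pluripotency genes lower (1 when adjusted over the list alone, Fgf15, −0.85 ± 0.20; adjusted p = 0.306 with an estimated correlation). With the replicate block 10 genes were called in LiTEC and 37 in WT, ATF4 targets (adjusted p = 0.0197) and ERK pathway feedback (0.0459) were also called lower in LiTEC. In WT the same held for ERK pathway feedback (0.0246) and Wnt targets (0.0416). None of these 4 calls was kept with the block and an estimated correlation (adjusted p = 0.435 and 0.248 in LiTEC and 0.156 and 0.122 in WT). Cbr3 missed the threshold without lit replicates 2 or 3 or dark replicates 1 or 2 and Gm48639 without any of the 6. The LiTEC count was thus 1 without lit replicate 1 and 0 without lit replicate 2 or 3 or dark replicate 1 or 2. The WT count was 13 without dark replicate 1 and 1 without dark replicate 2. DESeq2 called 8 genes in LiTEC, and 1, 0 and 3 were called there in batch 2 alone, without a batch term and among the compared groups. The difference between genotypes at 4 h called no gene by edgeR or DESeq2 (657 at an unadjusted p below 0.05; 16 without an expression filter). The 2 lists called in it, ribosomal proteins and unfolded protein response, had adjusted p = 0.75 with an estimated correlation and no member called, over all genes or over the list alone. The heat shock response list joined them with the block (adjusted p = 0.0443; adjusted p = 0.621 with the block and an estimated correlation).

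Averaged over the 3 times, with 9 lit and 9 dark libraries per genotype, light changed 341 genes in LiTEC (171 higher, 170 lower) and 321 in WT (148 higher, 173 lower). Of these 52 were higher in both and 51 lower in both, against 1.39 and 1.62 from independent lists. Hspa1a, Hspa1b, Dnajb1 (0.45 ± 0.05 in LiTEC, 0.54 ± 0.05 in WT), Socs3, the copper chaperone gene Cox17 (0.39 ± 0.07 and 0.43 ± 0.07), Thap2 and Arsk rose in both genotypes. Lefty1 (−0.59 ± 0.12 and −0.81 ± 0.12), Snhg4 and Rnf225 fell in both. In LiTEC 7 of 20 heat shock genes rose, with 12 when adjusted over the list alone (adjusted p = 0.00163 with an estimated correlation). So did 6 of 18 genes of the unfolded protein response, among them Hspa5 (0.24 ± 0.04) and Hsp90b1 (0.16 ± 0.03), with 12 when adjusted over the list alone (adjusted p = 0.00677 with an estimated correlation). In WT 4 of 20 heat shock genes rose (6 when adjusted over the list alone; adjusted p = 0.00318 with an estimated correlation). There 6 of 21 hypoxia and glycolysis genes fell, including Pdk1 (−0.20 ± 0.03), the glucose transporter gene Slc2a1 (−0.30 ± 0.06) and Ldha, with 14 when adjusted over the list alone (adjusted p = 0.0997 with an estimated correlation). Sox2 (−0.14 ± 0.04) and Tdgf1 of 26 pluripotency genes fell (5 when adjusted over the list alone; adjusted p = 0.0448 with an estimated correlation). Of the transcription machinery lists, Med1 (−0.15 ± 0.03) was the 1 of 32 Mediator genes called in LiTEC, and the P-TEFb cyclin gene Ccnt1 rose slightly in both genotypes (0.13 ± 0.03 and 0.12 ± 0.03); neither list was called. Lists called in LiTEC also included zinc (1 of 6 higher, 3 when adjusted over the list alone), p53 targets (3 of 19, 5), STAT3 targets (2 of 9, 2) and immediate early genes (5 of 27, 10), with adjusted p = 0.00475, 0.0156, 0.0156 and 0.0506 with an estimated correlation. The other 4 of the 10 lists called there held no called member: NRF2 (0 when adjusted over the list alone) and ribosomal proteins (0), higher, and cholesterol synthesis (1 lower) and hypoxia and glycolysis (0), lower, with adjusted p = 0.164, 0.712, 0.712 and 0.725 with an estimated correlation. In WT 11 lists were called, 5 higher and 6 lower. The higher ones besides heat shock were STAT3 targets (2 of 9 higher; 2 higher and 1 lower when adjusted over the list alone), zinc (1 of 6, 2), immediate early genes (1 of 27, 1) and the unfolded protein response (0 of 18, 0), with adjusted p = 0.104, 0.0605, 0.389 and 0.56 with an estimated correlation. The lower ones besides hypoxia and pluripotency were ribosomal proteins (2 of 34 lower, 7), G2/M genes (2 of 17 lower, 2), cholesterol synthesis (2 of 20 lower, 3) and formative pluripotency (2 of 15 lower, 2), with adjusted p = 0.137, 0.0997, 0.509 and 0.434 with an estimated correlation. The block gave 661 and 644 calls, no batch term 90 and 114, the compared groups alone 206 in WT, and batch 2 alone 8 and 76. In LiTEC the count was 173, 188, 220, 218 and 174 without lit replicate 1 at 0 h, lit replicates 1 or 3 at 1 h, dark replicate 2 at 1 h or dark replicate 1 at 4 h. Of the genes called in batch 2 alone, 7 of 8 in LiTEC and 74 of 76 in WT had the same direction in batch 1.

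The light effect changed over the 3 times for 9 genes in LiTEC and 117 in WT. Banp (0.31, 0.83 and −0.04 at 0, 1 and 4 h in LiTEC; adjusted p = 0.000102), Rsrp1, Socs3, Snhg4 and Zfp941 were called in both genotypes. The 9 of LiTEC also held Ripk4, Zfp296, Trpc5os and Gm36527, the last called in WT too. In WT the smallest p-values belonged to Lrrc75aos2, Gas5 (−0.96, −0.09 and −0.17; adjusted p = 2.09e-07), Snhg4 and Dancr. List members called in WT were 3 of 20 heat shock genes (4 when adjusted over the list alone), Junb and Socs3 of 9 STAT3 targets (2), Junb of 27 immediate early genes (5), Xbp1 of 18 unfolded protein response genes (4), Cyp51 of 20 cholesterol synthesis genes (2), Slc30a1 of 6 zinc genes (1) and Rpl24 of 34 ribosomal protein genes (1). In LiTEC Socs3 was the 1 called list member (2 STAT3 targets when adjusted over the list alone). Counts were 29 and 300 with the replicate block, 27 and 252 by DESeq2, 4 and 49 without a batch term, 2 and 7 in batch 2 alone, 60 and 292 without an expression filter, and 19 and 70 when only the compared groups were fitted. Without dark replicate 3 at 0 h they were 5 and 53, without lit replicate 2 at 0 h 76 in WT, and without lit replicate 1 or dark replicate 3 at 1 h or dark replicate 2 at 4 h 5 in LiTEC.

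Dark cells were not constant over the same hours, which is the background of the values above. Among dark libraries 1024 genes changed with time in LiTEC and 1857 in WT, and 597 were called in both, against 105 from independent lists; 485 of these had the same sign at 1 h and 569 at 4 h. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was higher at 4 h than at 0 h by 0.58 ± 0.10 in LiTEC and 0.72 ± 0.10 in WT, as were Mdm2 (0.39 ± 0.06 in both) and Btg2 (0.45 ± 0.10 and 0.38 ± 0.10). Of 19 p53 targets 8 and 10 changed, and 14 and 11 when adjusted over the list alone. Of 27 immediate early genes 6 and 11 changed (10 and 12 when adjusted over the list alone), such as Junb, −0.52 at 1 h and 0.52 at 4 h in LiTEC and −0.37 and 0.57 in WT. At 1 h in the dark, Banp (−0.33 in both genotypes), Rsrp1 (−0.49 and −0.33), Zfp296 (−0.72 in both), Socs3 (−0.36 and −0.33) and Junb were thus below their 0 h level. Their light effects at 1 h are measured from that lower level. In LiTEC and WT these were 0.83 and 0.78 for Banp, 0.55 and 0.47 for Rsrp1, 0.77 and 0.55 for Zfp296, 0.93 and 0.97 for Socs3 and 0.67 and 0.83 for Junb. Each was larger than the dark fall except for Zfp296 in WT, and only slightly so for Rsrp1 and Zfp296 in LiTEC. Banp stood at 42.5 ± 2.10, 33.9 ± 2.69 and 58.9 ± 2.04 CPM at 0, 1 and 4 h in dark LiTEC cells and at 52.8 ± 5.62, 60.3 ± 2.52 and 57.4 ± 3.54 CPM in lit ones.

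Germline regulator Prdm14, also a pluripotency factor, was lower at 4 h in the dark (−0.68 ± 0.11 in LiTEC, −0.37 ± 0.11 in WT), as 2 and 8 of 26 pluripotency genes changed (7 and 10 when adjusted over the list alone), but Pou5f1, Nanog, Sox2, Klf4 and Esrrb were not called. Of 18 unfolded protein response genes 4 and 7 changed (6 and 11 when adjusted over the list alone), with Hsp90b1 at −0.28 ± 0.05 and −0.30 ± 0.05 at 4 h. In LiTEC 6 of 20 cholesterol synthesis genes changed (10 when adjusted over the list alone; Mvd 0.34 ± 0.08 at 4 h), and in WT 3 of 13 mitochondrially encoded mRNAs did (7 when adjusted over the list alone; mt-Cytb −0.56 ± 0.11). Replicate 3 of dark WT cells at 4 h, with 26.1% of counts on Gm26917, had 1.14% of counts on mitochondrial genes, against 1.72% and 2.09% in replicates 1 and 2. Without it mt-Cytb was the 1 mitochondrial gene called (−0.40 ± 0.10; 2 when adjusted over the list alone), and in WT 5 p53 targets, 7 immediate early genes and 5 pluripotency genes were called (7, 10 and 6 when adjusted over the list alone). The clearest single changes, with both genotypes alike, were the splicing-related gene Rsrp1 (0.47 ± 0.06 and 0.57 ± 0.06 at 4 h), Ppp1r10 (−0.81 ± 0.10 and −0.87 ± 0.10) and Zfp296 (0.51 ± 0.09 and 0.37 ± 0.09). Among the rest named by the rule in both were Zfc3h1, Banp, Trim11, Pcf11 (−0.43 and −0.61), Nr4a1, Igsf9b, Phf13 and Ankrd52. The block gave 1819 and 3033 calls, no batch term 378 and 806, batch 2 alone 211 and 585, and the compared groups alone 397 in WT. The LiTEC count was 681, 660, 596, 558 and 516 without replicates 2 or 3 at 1 h or 1, 2 or 3 at 4 h. The WT count was 877 without replicate 3 at 4 h.

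**Figure D3:**
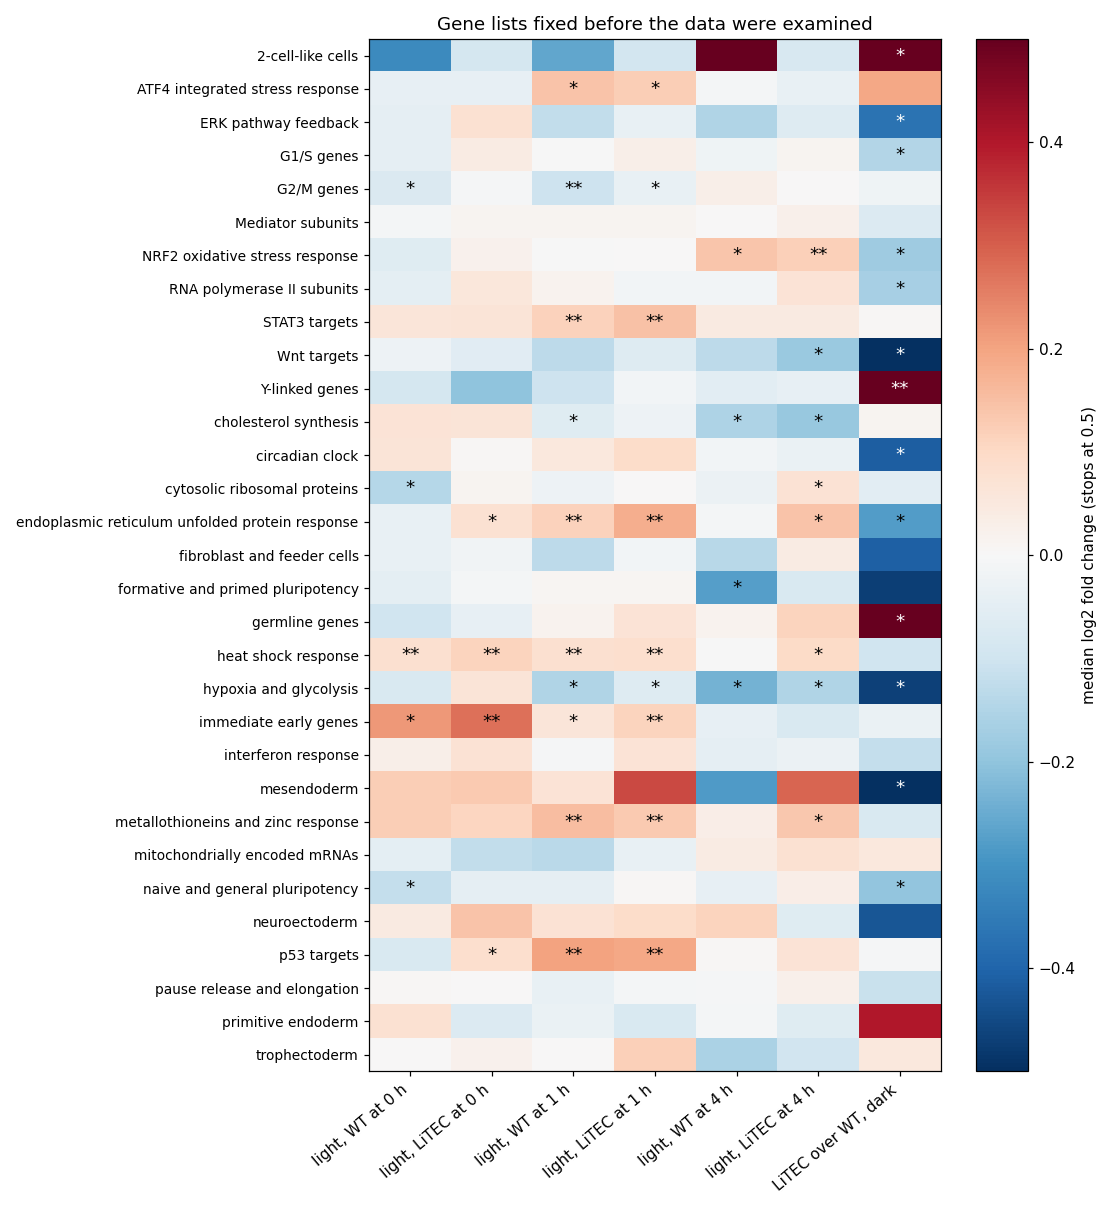
Median log2 fold change of the measured members of each of the 31 lists (y axis) in 7 comparisons (x axis), as a colour that stops at 0.5 in either direction; an asterisk marks a list called by camera and 2 asterisks a call kept with an estimated correlation. Heat shock genes are called with light at 0 and 1 h in both genotypes, with both asterisks.

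LiTEC and WT cells also differed without light. The design cannot tell an effect of LiTEC from other differences between the 2 cell populations. Over the 9 dark libraries of each genotype, 8655 of 18193 genes were called, 4341 higher and 4314 lower in LiTEC, most by small amounts (1051 with an absolute log2 fold change of at least 1). Csf3 (chromosome 11, 98701263 to 98703629), the gene of granulocyte colony-stimulating factor, had 2693 counts in LiTEC and 0 in WT, at least 1000-fold higher against a floor of 3 counts over the 9 WT libraries. The ferritin pseudogene Ftl2-ps, which lies inside Grik3 on the same strand, had 3 counts in LiTEC and 12617 in WT, 3774-fold lower with a 95% interval of 1291 to 18300 that covers counting error only. Epx, the eosinophil peroxidase gene, was at 20.2 ± 2.17 CPM in LiTEC and 0.179 ± 0.118 in WT (6.84 ± 0.17), followed by Unc80 (5.56 ± 0.21), Filip1, Lypd1, Lcp1, Armc2 and Ccdc148. The mesoderm regulator T was at 0.496 ± 0.297 CPM in LiTEC and 4.68 ± 1.26 in WT (−3.25 ± 0.24), followed among the lower genes by Ccnd2 (−2.81 ± 0.31), AC183095.1, Bcl11a (−2.60 ± 0.29), Vrtn, Tgm3, Nkx1-2, Soga3, Sall3 and Nrp2 (−1.84 ± 0.07).

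All 14 measured genes of the 2-cell-like state, a rare totipotent-like state of embryonic stem cell cultures, were higher in LiTEC, also over the list alone. Zscan4f (4.30 ± 0.64), Zscan4c (6.04 ± 4.12 against 0.394 ± 0.382 CPM; 4.02 ± 0.54), Zscan4e and Zscan4d were among the genes with the largest rises. They belong, like the Usp17l genes of the list, to families of near-identical copies (camera adjusted p = 8.04e-06; adjusted p = 0.34 with an estimated correlation). Of 12 germline genes 7 were higher and 1 lower, with Dazl at 0.89 ± 0.11 and Brdt at 1.56 ± 0.24 (adjusted p = 0.119 with an estimated correlation). Of 6 Y-linked genes 5 were higher, with Ddx3y at 0.69 ± 0.04 and Zfy1 at 2.40 ± 0.15 (adjusted p = 0.00697 with an estimated correlation). For these 2 lists the counts were the same when adjusted over the list alone.

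Of 21 hypoxia and glycolysis genes 17 were lower and 1 higher (19 and 1 when adjusted over the list alone), including Ldha (−0.73 ± 0.04), Pgk1 (−0.60 ± 0.05) and Gapdh (−0.21 ± 0.03; adjusted p = 0.119 with an estimated correlation). Of 18 unfolded protein response genes 13 were lower and 2 higher, with Pdia4 at −0.52 ± 0.03 (adjusted p = 0.0929 with an estimated correlation). Of 12 Wnt targets 7 were lower (8, with 1 higher, when adjusted over the list alone; Notum −1.42 ± 0.10, adjusted p = 0.0929 with an estimated correlation), and of 7 mesendoderm genes 6, with Fgf8 at −2.15 ± 0.30 (adjusted p = 0.0813 with an estimated correlation). Of 26 naive pluripotency genes 18 were lower, among them Nr5a2 (−0.51 ± 0.04), Klf4 (−0.39 ± 0.05), Sox2 (−0.32 ± 0.04), Nanog (−0.22 ± 0.06), Pou5f1 (−0.20 ± 0.06) and Esrrb (−0.16 ± 0.03). From the list 4 were higher, such as Tfcp2l1 (0.34 ± 0.02; 18 and 5 when adjusted over the list alone; adjusted p = 0.165 with an estimated correlation). Nanog was 0.06 in batch 1 and −0.35 in batch 2, and Eomes of the mesendoderm list (−0.50 ± 0.16) was 0.31 and −0.85. Other lists called lower were G1/S (10 lower, 2 higher of 17), circadian clock (10 and 1 of 16; 11 lower over the list alone), ERK feedback (7 and 2 of 13), NRF2 (11 and 4 of 19) and RNA polymerase II (7 and 1 of 12, with Polr2a at −0.36 ± 0.04), with adjusted p = 0.34, 0.0929, 0.462, 0.34 and 0.34 with an estimated correlation. With the replicate block the circadian (adjusted p = 0.0584), germline (0.0623) and NRF2 (0.0683) lists were no longer called and formative pluripotency was (0.014, from 0.0587; adjusted p = 0.139 with the block and an estimated correlation).

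The lists without a call in this comparison had members in both directions or few called members. Higher and lower members numbered 3 and 11 of 15 for formative pluripotency (Dnmt3a 0.95 ± 0.06, Lef1 −1.69 ± 0.15), 10 and 2 of 20 for ATF4 targets, 3 and 2 of 20 for cholesterol synthesis, 2 and 8 of 34 for ribosomal proteins, 1 and 2 of 17 for G2/M, 5 and 10 of 20 for heat shock, 7 and 7 of 27 for immediate early genes, 2 and 4 of 10 for interferon, 1 and 2 of 6 for zinc, 2 and 0 of 13 for mitochondrially encoded mRNAs, 5 and 7 of 19 for p53 targets and 3 and 4 of 9 for STAT3 targets. In the transcription machinery they numbered 8 and 11 of 32 for Mediator (Med25 −0.37 ± 0.03, Med16 0.45 ± 0.05) and 5 and 10 of 20 for pause release and elongation (Ell 0.55 ± 0.04). Markers of other cell types gave 8 and 3 of 14 for primitive endoderm (Gata4 0.88 ± 0.14, Sox7 −1.58 ± 0.24), 1 and 4 of 7 for neuroectoderm, 2 and 1 of 8 for trophectoderm (Ascl2 2.08 ± 0.26) and 1 and 5 of 9 for fibroblasts and feeders (Col1a1 −1.50 ± 0.27). When adjusted over the list alone, the counts differed for cholesterol synthesis (3 and 1), ribosomal proteins (2 and 5), G2/M (1 and 1), zinc (1 and 3), primitive endoderm (9 and 3) and fibroblasts (1 and 6). Actb (0.00 ± 0.03) was not called. Of 7014 genes called in batch 2 alone, 6539 had the same direction in batch 1.

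On 2 autosomes the median gene differed between the genotypes by more than on the rest. On chromosome 8 the median log2 fold change of LiTEC over WT was 0.263, with 531 of 781 genes higher and 37 lower, and on chromosome 6 it was −0.162, with 333 of 679 lower and 105 higher; the medians of the other 17 autosomes lay between −0.0598 and 0.0147. The shift of chromosome 6 was uneven: from the lowest to the highest tertile of expression its median was −0.0542, −0.162 and −0.233, and over 10 position bins it ran from −0.0183 in bin 1 to −0.243 in bin 6, whereas on chromosome 8 the tertiles had 0.323, 0.266 and 0.236 and the bins 0.173 to 0.340. Over all tested genes, without the 1 CPM minimum, the medians were 0.268 for chromosome 8 and −0.138 for chromosome 6. Each of the 18 LiTEC libraries, lit or dark, had a chromosome 8 median between 0.235 and 0.295 relative to the dark WT mean, and the 18 WT libraries lay between −0.0241 and 0.0287. The 7 chromosome Y genes with a mean of at least 1 CPM had a median of 0.694, and all 12 tested ones 0.706. The light effect in LiTEC at 0 h had a chromosome 8 median of 0.0275.

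**Figure D4:**
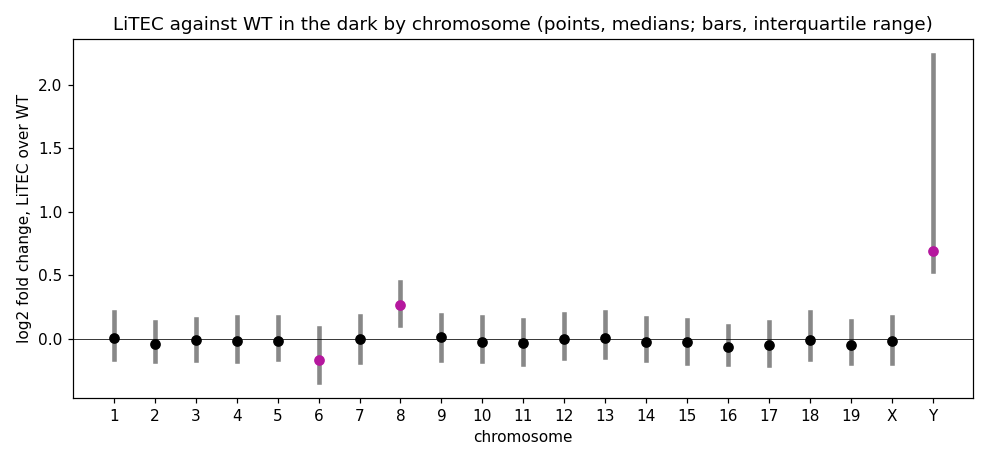
Median (point) and interquartile range (bar) of the LiTEC minus WT log2 fold change in the dark for the genes of each chromosome. Chromosome 8 lies above 0 (0.263) and chromosome 6 below (−0.162), apart from the other autosomes, and chromosome Y is highest (0.694).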

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

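The tests of position bins on chromosome 8, of long non-coding RNAs in general, of a fall of equal size in every snoRNA host, of warming and of the response size with the replicate block, and the use of quartiles in the tests of the dark baseline and of snoRNA hosts, were chosen only after the results they bear on had been seen; the other tests of the 3 patterns below were set beforehand. A difference between groups, shown by a test of that difference, sets apart the results of the first paragraph.

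The light effect at 0 h differed between LiTEC and WT for 4 genes: Lrrc75aos2 (1.70), Snord43 (1.45), Gas5 (0.52) and B830012L14Rik (−0.82). Over the 3 times it differed for 9 genes in LiTEC, with adjusted p = 0.000102 for Banp, 0.000395 for Rsrp1, 0.00741 for each of Zfp296, Socs3 and Ripk4, 0.0247 for Snhg4, 0.0332 for each of Trpc5os and Gm36527 and 0.0464 for Zfp941. In WT it differed for 117 genes, with adjusted p = 1.77e-08 for Lrrc75aos2, 2.09e-07 for Gas5, 5.26e-07 for Snhg4, 2.60e-05 for Dancr, 0.000128 for Hspa1b, 0.000222 for Hspa1a, 0.000467 for Snord43, 0.000575 for Snhg1, 0.00101 for Zfp386 and 0.00109 for Dpm1. The splits given below do not exclude chance for the 4, 9 or 117 genes. For the difference at 0 h, batch 2 alone called 0 genes, and the counts of Lrrc75aos2 and Snord43 are uncertain, as given above.

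The response to light at 0 h was smaller in LiTEC than in WT by count: of 977 genes that moved with light over both genotypes together, 619 (63.4%) had the larger change in WT, with median absolute changes of 0.36 and 0.45, and the mean change was smaller in LiTEC within each replicate number (0.43 and 0.49, 0.33 and 0.43, 0.45 and 0.55). The LiTEC library with the larger share of the ribosomal RNA locus is excluded as the cause, since the figure is 64.7% of 742 genes without it. A raised dark baseline in LiTEC stays open: the genes that rose had a median difference of −0.0219 there in the dark, below the bound of 0.5 times the shortfall (0.0747) set beforehand, but that bound took no account of spread, and the quartiles of −0.187 and 0.179 span the shortfall. Spread between libraries stays open too, because the sets of genes that rose and fell had p = 0.0227 and p = 0.0623 in the interaction with an estimated correlation, and p = 0.0230 and p = 0.0821 with the replicate block, which takes same-numbered libraries as related; so does an effect of LiTEC on the response, the biological explanation that the design names.

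Chromosome 8 genes were higher in LiTEC in the dark by a median of 0.263. A scaling difference would shift the other autosomes as well. The largest absolute median among the autosomes other than 6 and 8 was 0.0598. Chromosome 6, left out of this check, had a median of −0.162, in the opposite direction. A shift shared by all chromosomes is thus excluded as the source of the chromosome 8 value. A few strongly changed genes or one region are excluded too, since 10 of 10 position bins had a median above 0.1 (0.17 to 0.34). An extra copy of the chromosome in part of the LiTEC cells would raise weakly and strongly expressed genes alike. From the lowest to the highest tertile of expression the medians were 0.323, 0.266 and 0.236. The smallest of them met the bound set beforehand, as such a copy would give. Whether copies differ would have to be shown on DNA.

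Of 27 non-coding RNAs with a small nucleolar RNA (snoRNA) gene inside them on the same strand, a set without Snhg4, which the annotation did not match, 13 were called lower and 1 higher with light at 0 h in WT (median −0.53), and 6 lower in LiTEC (median −0.25). A fall of equal size in long non-coding RNAs in general is excluded, since sets matched on expression had a median of −0.0376 in WT. The WT median of the hosts lay at percentile 0.009999 of 10000 such sets, the lowest value that this number of sets allows. Hosts such as Gas5 and Dancr had been seen among the largest falls in these same values, so the percentile is not independent support for the pattern. The 214 protein-coding hosts lay at percentile 0.16 of matched sets in WT, as a fall of every transcript that carries snoRNAs would give, but a test added after that percentile was seen excludes a fall of equal size, with a median of −0.0436 and quartiles of −0.110 and 0.0371. Warming of the lit cells cannot be told apart from light itself. The heat shock list without Hspa1a and Hspa1b was higher (larger p = 0.0125 of the 2 genotypes with an estimated correlation). Warming would lower the cold-induced genes Cirbp and Rbm3, and both had negative values in both genotypes, but only Cirbp in WT was called. Cirbp was −0.42 ± 0.12 in WT (adjusted p = 0.0499) and −0.44 ± 0.12 in LiTEC (adjusted p = 0.0793), and Rbm3 −0.17 ± 0.06 and −0.10 ± 0.06.

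Other splits of the same libraries were fitted in the same way. For the light effects within a genotype at 1 time, 3 lit against 3 dark libraries allow 10 splits, too few for a share under 0.05. The real and the highest other counts were 170 and 0, 21 and 10, and 2 and 0 in LiTEC at 0, 1 and 4 h, and 520 and 0, 52 and 0, and 0 and 0 in WT; as many genes were called by 1 of the 10 splits in each case except WT at 4 h, where all 10 gave as many. Only the real split called as many genes for LiTEC against WT in the dark (8655, highest other 5821, 1 of 61 splits). The same held for time in the dark in LiTEC (1024 and 554, 1 of 25) and in WT (1857 and 326, 1 of 25). It also held for the mean light effect in LiTEC (341 and 3, 1 of 30) and in WT (321 and 43, 1 of 30). These shares are the smallest that the numbers of splits allow. The splits deal out single libraries as unrelated, although same-numbered libraries are related. A share under 0.05 therefore does not exclude chance here. A share of 0.05 or more called as many genes for the difference of light effects at 0 h (4 and 977, 3 of 21), at 1 h (0 and 1, 21 of 21) and at 4 h (0 and 0, 21 of 21). So it was for the light effect over time in LiTEC (9 and 248, 5 of 25) and in WT (117 and 1020, 2 of 25). Chance cannot be excluded for these either. The split with 977 genes exchanges lit and dark libraries in 1 genotype, so it measures the light effect common to both. For the light effect over time, the splits of both kinds dealt out the times among lit and among dark libraries separately. Changes over time that lit and dark cells share can therefore enter the counts, such as the 248 and 1020 genes. These splits thus cannot decide whether the 9 and 117 genes arose by chance, and what the splits with the highest counts share was not tested. Against splits that part as many of the numbered pairs as the real one, which mix conditions within a number, the highest counts were 136 for the difference at 0 h, 362 and 240 for the light effect over time, 6274 for LiTEC against WT, 649 and 1377 for time in the dark and 80 and 168 for the mean light effect.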

How the results depend on the processing

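A replicate block per genotype, a fit without the ribosomal RNA loci, the block with an estimated correlation for lists, leaving out each library for lists and chromosome medians, and leaving out replicate 3 of dark WT at 4 h for list members over time were chosen only after the data had been seen. In the order LiTEC at 0, 1 and 4 h and WT at 0, 1 and 4 h, light changed 290, 60, 10, 870, 111 and 37 genes with the replicate block, 437, 118, 33, 1098, 193 and 94 with a block per genotype, and 3, 7, 1, 141, 11 and 0 in batch 2 alone, where fewer libraries are compared. Without a batch term the counts were 73, 10, 0, 277, 15 and 0. Fitting the compared groups alone gave 71 in LiTEC and 178 in WT at 0 h and 20 in WT at 1 h. DESeq2 gave 45 and 8 in LiTEC at 1 and 4 h and 18 in WT at 4 h. No expression filter gave 50, 36, 104 and 113 in LiTEC and WT at 1 and 4 h, and a batch effect per genotype 36 in LiTEC at 1 h and 5 in WT at 4 h. A mean of at least 5 CPM gave 1 in LiTEC and 4 in WT at 4 h, and leaving out the ribosomal RNA loci 3 in WT at 4 h. A log2 fold change of at least 1 left 34, 5, 1, 134 and 8 genes, in the same order up to WT at 1 h, by its construction.

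The difference of light effects at 0 h gave 7 genes with the block, 9 with a block per genotype, 0 in batch 2 alone (edgeR), 31 without an expression filter and 2 at the fold threshold; without the filter, 4 and 16 were called at 1 and 4 h. LiTEC against WT left 1051 at the fold threshold. For the light effect over time, LiTEC and WT gave 29 and 300 with the block, 54 and 519 with a block per genotype, 4 and 49 without batch, 2 and 7 in batch 2, 27 and 252 by DESeq2, 60 and 292 without the filter and 19 and 70 from the compared groups. Time in the dark gave 1819 and 3033, 2384 and 3750, 378 and 806, and 211 and 585 for the first 4 of these, and 397 in WT from the compared groups. The mean light effect gave 661 and 644, 944 and 933, 90 and 114, and 8 and 76, with 206 in WT from the compared groups and 13 and 7 at the fold threshold. Of 372 list tests 85 were called, 24 with an estimated correlation and 35 with the block and an estimated correlation. The chromosome 6 median was −0.191 at a mean of at least 5 CPM. Apart from alternatives that change the genes or libraries by construction, the cause was not tested.

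Leaving out each library in turn gave 40 to 128, 9 to 35 and 0 to 2 genes for light in LiTEC at 0, 1 and 4 h, and 233 to 460, 16 to 38 and 0 to 13 in WT. It gave 1 to 5 for the difference at 0 h, 0 at 1 and 4 h, 8168 to 8558 for LiTEC against WT, 5 to 11 and 53 to 138 for the light effect over time, 516 to 917 and 877 to 1936 for time in the dark, 173 to 427 and 225 to 406 for the mean light effect, 73 to 90 lists, 0.255 to 0.275 for chromosome 8 and −0.170 to −0.151 for chromosome 6. A group left with 2 libraries is assumed to vary like the others. No named gene changed direction past the threshold: over all these fits 7937 values kept their side of it, 531 lost the call and 40 gained it, and with the block 670 kept their side, 42 gained a call and 0 lost one. The block changed no call of a list beyond those given with the results and, for the mean light effect, G1/S genes in LiTEC (adjusted p = 0.04996, from 0.0992) and Wnt targets in WT (0.0442, from 0.283), with adjusted p = 0.442 and 0.152 with the block and an estimated correlation.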

Other observations

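The lists of imprinted genes, clustered protocadherins and Hox genes were chosen only after the values of LiTEC against WT had been seen. In that comparison 47.6% of all 18193 tested genes were called, 4341 higher and 4314 lower in LiTEC. The number of called members alone thus does not set a list apart. Imprinted genes, which are expressed from 1 parental copy, differed in both directions in the dark, with 14 of 40 measured higher in LiTEC and 10 lower. Among them were the paternally expressed neighbours Peg10 (1.46 ± 0.17) and Sgce (1.70 ± 0.15), Plagl1 (1.48 ± 0.11), H19 (1.41 ± 0.18) and Slc38a4 (0.92 ± 0.09), all higher, and Igf2 (−2.51 ± 0.33) and Nnat (−1.51 ± 0.13), lower. Nnat lies within the bounds of Blcap (−0.16 ± 0.05), so its counts are uncertain. As a list they had no common direction (p = 0.244 with an estimated correlation).

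Hox genes, which pattern the body axis, were higher in LiTEC in 8 of 13 cases and lower in none. The HoxC cluster held several: Hoxc8 (1.67), Hoxc11 (1.39), Hoxc9 (1.36), Hoxc12 (1.16) and Hoxc13 (0.85). The list had p = 0.0786 with an estimated correlation. Clustered protocadherins, cell adhesion genes of which many share constant exons, were higher in 17 of 22 cases and lower in none (p = 0.162 with an estimated correlation), and counts of single members are uncertain for that reason.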
